A study of Mus musculus with 29 samples.

How the data were processed

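Chromatin accessibility was measured by ATAC-seq in embryonic mouse cortex at E14.5 (17 libraries) and in adult prefrontal cortex (12 libraries) from a line carrying a knockout of Myt1l, a zinc finger transcription factor of neurons. ATAC-seq uses a transposase that inserts adapters into open DNA, so that the number of reads in a region reflects how accessible it is. Libraries were grouped by the genotype in the labels: WT, Het (1 mutant allele) and Hom (2 mutant alleles). Litter was taken from the labels for embryos and sex from the labels for adults. The sex of the embryos is not given in the sources used here. The labels number the libraries and do not say that each is a separate animal, so p-values measure the spread between libraries.

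The authors deposited 1 table per tissue. Each holds log2 CPM, library-scaled counts, for numbered regions after an RUVr adjustment, as the deposited tables are titled. RUVr estimates factors of unwanted variation from residuals after the groups are fitted and removes them. Reads were processed against mm10, per the submitters' processing notes, which also name Trimmomatic, Bowtie2, STAR and HTSeq with no role or version. The peak caller, the number of RUVr factors and any shift of reads for the transposase are not given in the sources used here. The labels' protocol cites a published ATAC-seq method for the libraries and RNA kits that belong to another assay.

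The deposited log2 values were examined before any test. In each library 2 to the power of the value was set against an evenly spaced grid, with a tolerance of 0.1 of a step. All E14.5 values (100%) and at least 99.9996% of the adult values of each library lay on it. All libraries of a table had the same upper quartile, 4.61 CPM at E14.5 and 4.64 CPM in the adult. The sums over regions ran from 988155 to 1045790 CPM at E14.5 and from 994270 to 1041640 CPM in the adult. The grid was counted from the lowest value of each library. The lowest value of the E14.5 set was 0.101 CPM, at steps of 0.05011 to 0.05067 CPM. In the adult it was 0.0775 CPM, at steps of 0.03865 to 0.03898 CPM. Adjusted counts rounded to whole numbers and scaled to a common upper quartile would give such values. Because the lowest value lies above 1 step, an amount may have been added to the counts before the log. The sequencing depth behind each library is unknown, so no counting interval is given. Replicates were compared before averaging: correlations of log2 values ran from 0.957 to 0.983 within E14.5 groups and from 0.956 to 0.992 within adult genotypes, and 0 pairs of libraries were identical.

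Each table was also decomposed into its directions of variation among libraries. In each of them, 3 directions held almost no variation: their root mean square was 0.0113 to 0.0155 log2 at E14.5, against 0.265 to 0.341 in the other 13, and 0.0079 to 0.0116 in the adult, against 0.223 to 0.354 in the other 8. These are taken here as the variation that the authors' adjustment removed. The removed space held 0.00868% of the Het and 0.0148% of the Hom difference at E14.5, and 0.0667% of the genotype and 0.0844% of the sex difference in the adult. It held 64.6% of the difference between litters and 68.7% of the genotype by sex term. Tests that do not count these directions have 3 residual degrees of freedom too many, and tests of the genotype by sex term run on values from which most of that term was taken. A fit with the 3 removed directions as covariates was therefore added after the data were examined.

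Regions with a mean of at least 1 CPM were tested, 138760 of 205908 at E14.5 and 173029 of 237287 in the adult. The test was limma 3.58.1 in R 4.3.3 with an empirical Bayes trend, and a region was called at a Benjamini-Hochberg adjusted p under 0.05. One fit over all 17 libraries gave the E14.5 comparisons and the trend per mutant allele. In the adult, genotype and sex were fitted together, and a mean per genotype and sex gave the within-sex effects and their difference. The design fixed before the data were examined was written for log2 of CPM plus a pseudocount of 0.5. Because the deposited unit is already log2, the main test used the values as deposited. Pseudocounts of 0.1, 0.5 and 2 added to CPM became alternatives, on top of any amount already in the values. With the pseudocount of 0.5 the Het comparison called 1754 regions at E14.5 and 862 in the adult.

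The rule for named items asked for the largest rises and falls among called regions, with their genes. The deposited tables do not pair region numbers with genes or coordinates, so at most 2 regions that rose and 2 that fell are named per comparison, by their identifiers as deposited. The gene lists, location classes, sequence motifs, the comparison of regions between ages, a fit without X and Y, and the Myt1l promoter are not analysed here for the same reason. The targeted gene therefore could not be used to check the genotype labels.

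Single values were compared by two-sided exact permutation tests. Comparisons that share the WT libraries were set against simulations of unchanged groups. In 100 draws noise was shared between regions, as random mixtures of the 11 directions left in the residuals. In 100 more it was independent per region. The second kind was added after the result of the first was seen. The test was tested on simulated data with 200 changed regions. For the E14.5 Het comparison it recovered 24% of changes of 0.5 log2 and 79% of changes of 1 log2, with 3 false calls. For the adult Het comparison it recovered 21% and 84%, with 1 false call. In simulated tables without a genotype effect from which 3 factors unrelated to genotype had been removed, 8.43% of E14.5 and 11.5% of adult regions had an unadjusted p under 0.05, and 0 and 41 regions were called. With the removed directions as covariates these shares were 5.10% and 5.19%, with 0 called in both. Where the simulated factors were related to genotype, 29975 E14.5 and 40861 adult regions were called with no true effect, and 17868 and 14025 with the covariates. The strength of those factors was assumed, so these counts show only that the adjustment can leave such variation in a genotype contrast.

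Alternatives fixed before the data were examined were the pseudocounts, no filter or a filter at 2 CPM, trimmed mean scaling (30% of log ratios and 5% of levels trimmed, computed here on CPM), quantile normalization, an adjusted p under 0.1, robust limma, leaving out each library, litter as a block, each litter alone, the 2 groups alone and no sex term. Added later were the removed directions, removal of each library's level trend (a lowess curve with a span of 0.2 against the mean log2 level), both together, and the mean of a block of variable regions as a covariate. Labels say that a litter number marks a shared litter, so litter was treated as a block in that alternative. The main fit has no litter term. The adjustment had already taken most of the litter difference, as given above.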

Results

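Accessibility was compared between genotypes of a Myt1l knockout mouse line to ask how chromatin changes when this neuronal transcription factor is reduced or lost. The embryonic set comprised 6 WT, 5 Het and 6 Hom libraries of E14.5 embryonic cortex, of which 4 WT, 3 Het and 4 Hom came from litter 1 and 2 of each genotype from litter 2. The adult set comprised 6 WT and 6 Het prefrontal cortex libraries, with 3 males and 3 females of each genotype. Values were log2 CPM per region after the authors' adjustment for unwanted variation, with the same upper quartile in all libraries of a set, and the original depth of each library is unknown. Median levels per library were 1.65 to 1.72 CPM at E14.5 and 2.01 to 2.07 CPM in the adult. The first principal component held 10.1% of the variance at E14.5 and 21.2% in the adult, where all 6 males lay on one side and all 6 females on the other.

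**Figure D1:**
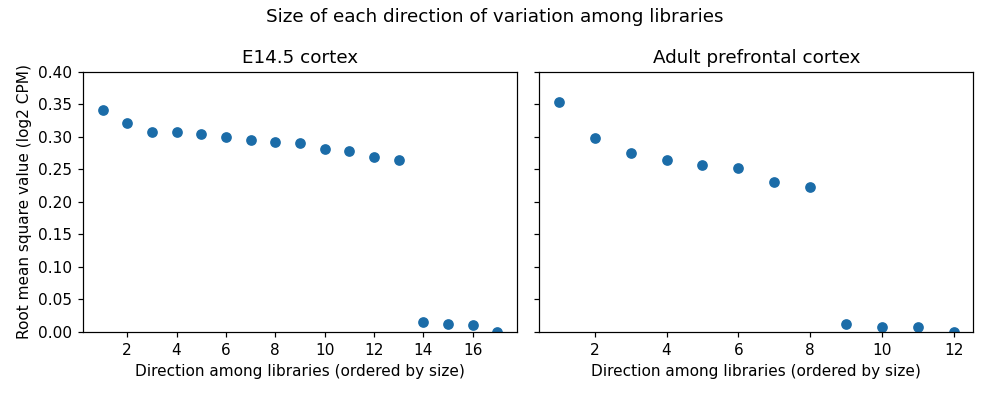
Root mean square value in log2 CPM (vertical axis) of each direction of variation among libraries, in order of size (horizontal axis), for 17 E14.5 and 12 adult libraries. At E14.5, 13 directions lie between 0.265 and 0.341 and 3 at or below 0.0155; in the adult, 8 lie between 0.223 and 0.354 and 3 at or below 0.0116; the last point of each panel is the mean, which was subtracted.

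In E14.5 cortex, libraries with 1 mutant Myt1l allele (Het) differed from WT at 1691 of 138760 regions, of which 555 rose and 1136 fell. Most changes were small: the median size among called regions was 0.31 log2 and only 14 exceeded 1 log2. The region all_e14_peak_169208 rose by 1.20 log2 in Het (SE 0.27, limma adjusted p = 0.0189), from 0.746 ± 0.382 CPM in 6 WT libraries to 1.62 ± 0.484 CPM (SD) in 5 Het libraries. The region all_e14_peak_22391 rose by 1.11 log2 (SE 0.25, limma adjusted p = 0.0192), from 0.880 ± 0.353 to 1.79 ± 0.386 CPM. The region all_e14_peak_21646 fell by 1.74 log2 (SE 0.46, limma adjusted p = 0.0467), from 2.27 ± 1.14 to 0.889 ± 0.780 CPM. The region all_e14_peak_72104 fell by 1.20 log2 (SE 0.26, limma adjusted p = 0.0189), from 1.24 ± 0.445 to 0.556 ± 0.240 CPM. All 4 regions lie near the filter of 1 CPM, and at all but all_e14_peak_22391 single WT and Het libraries overlapped. Their fold changes depend on the pseudocount: with 0.5 added to CPM they were 0.79, 0.76, -1.08 and -0.71 log2 in the order given, all still called.

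**Figure D2:**
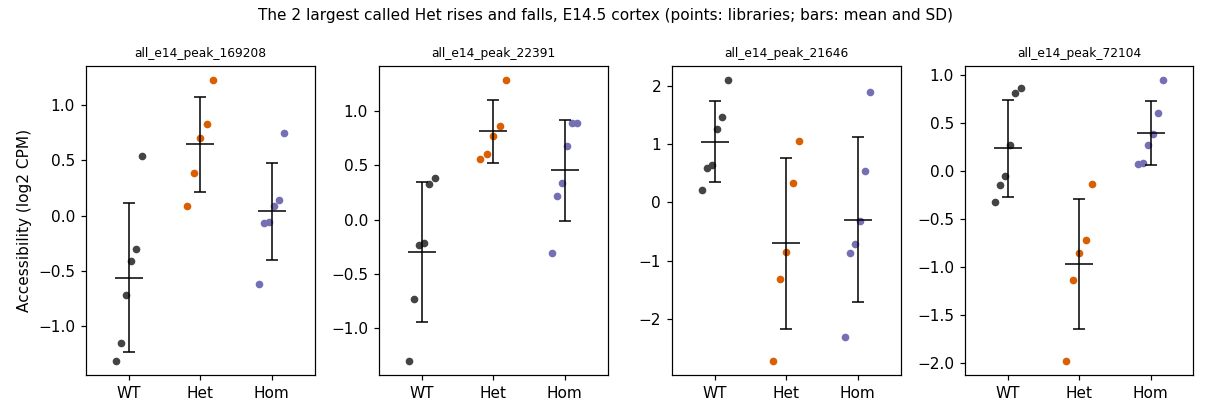
Accessibility in log2 CPM (vertical axis) of the 2 called regions with the largest Het rises and the 2 with the largest falls at E14.5, for WT (n = 6), Het (n = 5) and Hom (n = 6) libraries (points), with mean and SD (bars). The first 2 regions were higher and the last 2 lower in Het than in WT, while all_e14_peak_72104 in Hom lay near WT.

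The number of Het calls depended on how the variation was counted. With the 3 removed directions as covariates, 170 regions were called, 71 higher and 99 lower, and all 170 were among the 1691; the fold changes stayed at a median of 0.31 log2 while the median SE went from 0.07 to 0.08. With litter as a block, 1122 regions were called (362 higher, 760 lower), with litter 1 alone 130 (43 higher, 87 lower) and with litter 2 alone, which holds 2 libraries per genotype, 29 (26 higher, 3 lower). The direction also depended on scaling: after quantile normalization 388 regions were higher and 180 lower, and with each library's level trend removed 352 were higher and 140 lower. Leaving out single libraries moved the count to 203 without Het replicate 34, 948 without Het replicate 31, 756 without Het replicate 49 and 791 without Het replicate 64. It moved to 456 without WT replicate 25, 769 without WT replicate 10, 818 without WT replicate 43 and 1077 without WT replicate 57.

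Regions that fell in Het were mostly the most accessible ones. Of the 1136 regions that fell, 632 (55.6%) lay in the top decile of accessibility (odds ratio 11.8, 95% confidence interval 10.4 to 13.3, over regions that are not independent), against 49 (8.83%) of the 555 that rose. The median Het change ran from 0.05 log2 in the lowest decile of regions to -0.08 log2 in the highest. Among the 47 regions above 128 CPM, 11 rose and 2 fell, and their median change was -0.06 log2. The slope of each library's deviation against level was 0.0117 ± 0.00673 (SD, n = 6) in WT, -0.0154 ± 0.00587 (n = 5) in Het and 0.00115 ± 0.00509 (n = 6) in Hom, in log2 per log2. Het differed from WT (exact permutation p = 0.00433, adjusted 0.0108) and from Hom (exact permutation p = 0.00216, adjusted 0.0108), and Hom from WT (exact permutation p = 0.0173, adjusted 0.0289), in a family of 5 two-sided tests. In the adult the slope did not separate Het from WT (exact permutation p = 0.669, adjusted 0.669) or males from females (exact permutation p = 0.323, adjusted 0.403). The 5 slope tests were not in the design fixed before the data were examined. The adjustment kept the groups and removed variation within them, so their p-values may be too small.

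**Figure D3:**
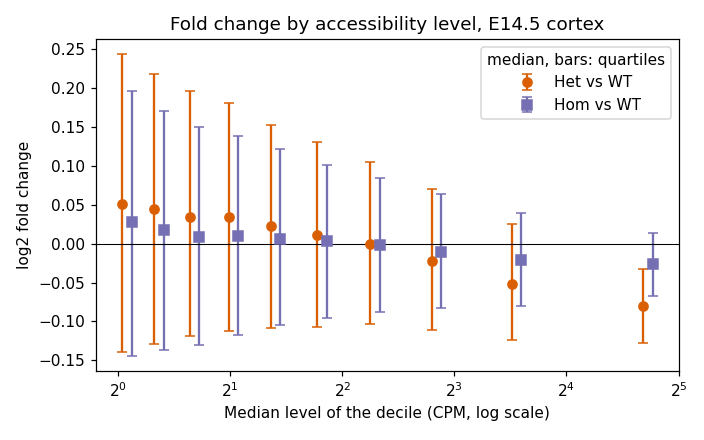
Median log2 fold change against WT (vertical axis, bars from the lower to the upper quartile) in deciles of the 138760 tested regions ordered by accessibility (horizontal axis, CPM, log scale), for Het and Hom at E14.5. The Het median falls from 0.05 to -0.08 and the Hom median from 0.03 to -0.03.

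Hom libraries, with 2 mutant alleles, differed from WT at no called region at E14.5. In the Hom comparison, 12926 of 138760 regions (9.32%) had an unadjusted limma p under 0.05, the smallest adjusted p was 0.121, and 0 regions passed. The regions named above differed in Hom by 0.60 log2 (SE 0.25) for all_e14_peak_169208, 0.75 (SE 0.23) for all_e14_peak_22391, -1.34 (SE 0.44) for all_e14_peak_21646 and 0.16 (SE 0.25) for all_e14_peak_72104, none of them called. A trend per mutant allele over all 17 libraries also called 0 regions, with 11587 (8.35%) at an unadjusted limma p under 0.05. In litter 2 alone, with 2 libraries per genotype, the Hom comparison called 20 regions and the trend 15; without Hom replicate 54 the Hom comparison called 1. With the removed directions as covariates both counts stayed at 0, and 5.74% and 5.23% of regions had an unadjusted p under 0.05.

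The direct comparison of Hom with Het, which asks whether the second mutant allele adds a change, called 29 regions, 11 higher and 18 lower in Hom. Of the 18 regions lower in Hom, 9 lay in the top decile of accessibility, as did 3 of the 11 higher ones, while the median change over all regions of that decile was 0.05 log2; the median size of the 29 changes was 0.42 log2. With the removed directions as covariates 18 regions were called, 14 of them among the 29, and the split went to 17 higher and 36 lower after quantile normalization and to 14 higher and 46 lower with the level trend removed. The count was 10 without Het replicate 64 or Hom replicate 54, 11 without Het replicate 34, 17 without Het replicate 31, 18 without Hom replicate 6 or 20, and 19 without Hom replicate 40.

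At the 1691 regions called in Het, the Hom difference had the same sign in 1628 (96.3%) and was smaller in 1673 (98.9%). Both comparisons share the WT libraries, and unchanged groups simulated against shared controls gave the same sign at 96.3% (87.4% to 100% over 20 draws) of the 1691 strongest regions with noise shared between regions, and at 93.5% (92.5% to 94.2%) with independent noise. In the same simulations the second difference was smaller at 94.2% (78.2% to 100%) and 96.6% (95.7% to 97.5%) of these regions. The observed shares lie within the first kind of range and above the second. Over all tested regions the Het and Hom differences correlated at r = 0.51 (across regions, which are not independent replicates). Unchanged groups gave 0.48 ± 0.25 (SD, 100 draws) with shared noise, of which 56 draws were as high, and 0.48 ± 0.00330 with independent noise, of which 0 were. The covariance was 0.0175 against 0.0154 ± 0.00972 with shared noise and 0.0144 ± 0.000148 with independent noise. With the 6 WT libraries split 3 to each comparison, r averaged 0.13 (0.08 to 0.23 over 20 splits), against a simulated mean near 0 with an SD of 0.30 for shared and 0.00409 for independent noise. The shared noise is a random mixture of the 11 directions left in the residuals, so its spread is wide by construction. Independent noise leaves out any correlation between regions. The simulations therefore do not decide whether Het and Hom share an effect.

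In adult prefrontal cortex, Het mice differed from WT at 803 of 173029 regions, of which 371 rose and 432 fell. The median size among called regions was 0.38 log2 and 2 exceeded 1 log2. The region all_pfc_peak_242747 rose by 2.37 log2 (SE 0.53, limma adjusted p = 0.0495), from 0.567 ± 0.776 to 1.53 ± 0.697 CPM (SD, n = 6 each), with 2 WT libraries at the lowest value of the table. That fold rests on the lowest value: with 0.5 added to CPM it was 1.10 log2 and with 2 added 0.48 log2, and neither was called. The region all_pfc_peak_242705 rose by 1.47 log2 (SE 0.33, limma adjusted p = 0.0484), from 2.01 ± 1.81 to 4.71 ± 2.82 CPM. The region all_pfc_peak_101467 fell by 0.86 log2 (SE 0.19, limma adjusted p = 0.0495), from 1.38 ± 0.303 to 0.787 ± 0.270 CPM. The region all_pfc_peak_101581 fell by 0.81 log2 (SE 0.16, limma adjusted p = 0.0357), from 1.39 ± 0.122 to 0.819 ± 0.254 CPM. With 0.5 added to CPM the last 3 regions changed by 1.15, -0.56 and -0.54 log2, all still called. With 2 added, all_pfc_peak_242705 changed by 0.74 log2 and was not called, while the 2 falls, at -0.28 and -0.27 log2, still were. At each of these named regions single WT and Het libraries overlapped. The 2 named rises lie among the last 100 region numbers, which are taken up under other observations. Among regions that fell, 126 of 432 (29.2%) lay in the top decile of accessibility (odds ratio 3.73, 95% confidence interval 3.0 to 4.6), against 32 of 371 (8.63%) that rose.

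**Figure D4:**
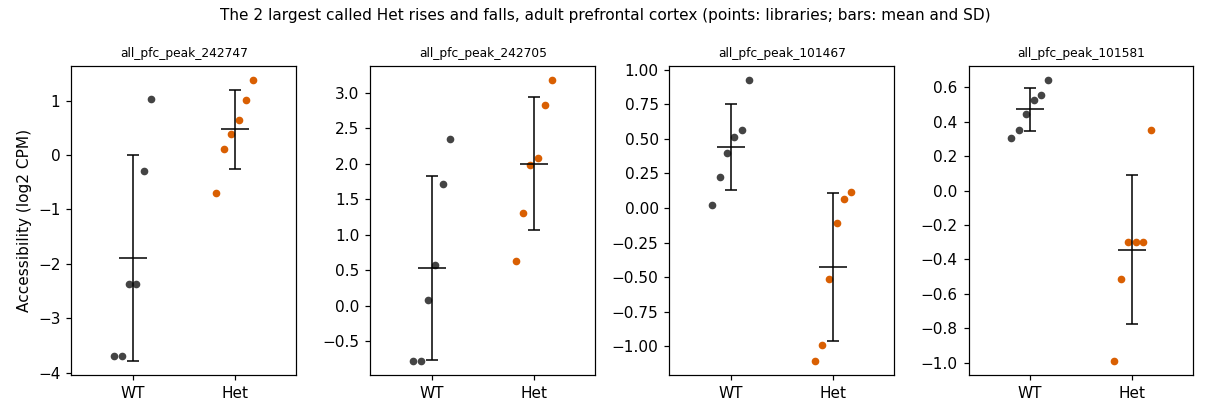
Accessibility in log2 CPM (vertical axis) of the 2 called regions with the largest Het rises and the 2 with the largest falls in adult prefrontal cortex, for WT and Het libraries (points, n = 6 each), with mean and SD (bars). The first 2 regions were higher and the last 2 lower in Het, and the WT libraries of all_pfc_peak_242747 spread with an SD of 1.90 log2.

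The number of adult Het calls stayed within 1.5 times of 803 in 8 of 25 alternative settings and moved further in 17. With the level trend removed 1217 regions were called, 788 of them among the 803. With the removed directions as covariates 24 regions were called, 14 of them among the 803: the fold changes kept a median of 0.38 log2 while the median SE went from 0.08 to 0.11. The 2 named rises stayed called there (adjusted p = 0.000422 and 0.000288 in limma) and the 2 named falls did not (adjusted p = 0.206 and 0.218). Unlike the median, the SE of the rises went down, at nearly the same fold. It went from 0.53 to 0.37 at all_pfc_peak_242747 and from 0.33 to 0.22 at all_pfc_peak_242705. Without a sex term 4 regions were called, and with quantile normalization 1242 (650 higher, 592 lower). The count was 3 without WT replicate 1, 27 without WT replicate 58, 55 without WT replicate 62, 139 without WT replicate 28 and 207 without WT replicate 35. It was 4 without Het replicate 44, 32 without Het replicate 21, 90 without Het replicate 47, 334 without Het replicate 11 and 333 without Het replicate 50.

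Within each adult sex no region was called. In males 11809 regions (6.82%) and in females 10166 (5.88%) had an unadjusted limma p under 0.05, and 0 passed in either. The difference between the sexes in the Het effect called 0 regions, and 67 regions (0.0387%) had an unadjusted limma p under 0.05. That share lies far below the 5% of a test without effects, and 68.7% of this term lay in the directions removed by the adjustment. The effects within males and within females each hold part of this term, so their tests share this limit. With those directions as covariates, 32 regions were called in males (median size 1.81 log2), 0 in females and 14 for the difference. These sizes are estimated from the part of the term that was left and are not changes measured in full. Because most of the term was removed, these values do not settle the Het effect within either sex, or whether it differs between the sexes.

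Males and females differed at 12543 of 173029 adult regions, 6291 higher in males and 6252 higher in females. The comparison was planned as a check of the sex labels. Its regions were picked by those same labels and have no coordinates on X or Y, so it is no independent check. The region all_pfc_peak_242735 measured 12.6 ± 4.0 CPM in 6 males and 0.123 ± 0.0620 CPM in 6 females, 3 of which were at the lowest value of the table. The region all_pfc_peak_242740 measured 7.90 ± 1.80 CPM in males, while all 6 females were at the lowest value, 0.0775 CPM, so no fold is given. The region all_pfc_peak_238320 was lower in males by 3.50 log2 (-3.50, SE 0.25, limma adjusted p = 1.02e-08), at 0.627 ± 0.280 against 6.45 ± 1.19 CPM. The region all_pfc_peak_240297 differed by -2.98 log2 (SE 0.10, limma adjusted p = 1.70e-14), at 1.20 ± 0.179 in males against 9.31 ± 0.462 CPM in females. The largest differences were few: the 8 regions higher in males by over 4 log2 were numbered 242733 to 242741, and the 21 higher in females by over 2 log2 were numbered 238307 to 240299. The cutoffs for these 2 sets differ and were chosen after the values were seen. Of all calls, 55 exceeded 1 log2, 20 of them numbered below 238307. Of the 12488 calls of at most 1 log2, 1.86% were numbered 238307 or above, near the 1.80% of all tested regions. With the removed directions as covariates 3135 regions were called, 3124 of them among the 12543; the count was 5231 without WT replicate 1, 7092 without Het replicate 44, 7857 without Het replicate 21 and 8028 without WT replicate 62.

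**Figure D5:**
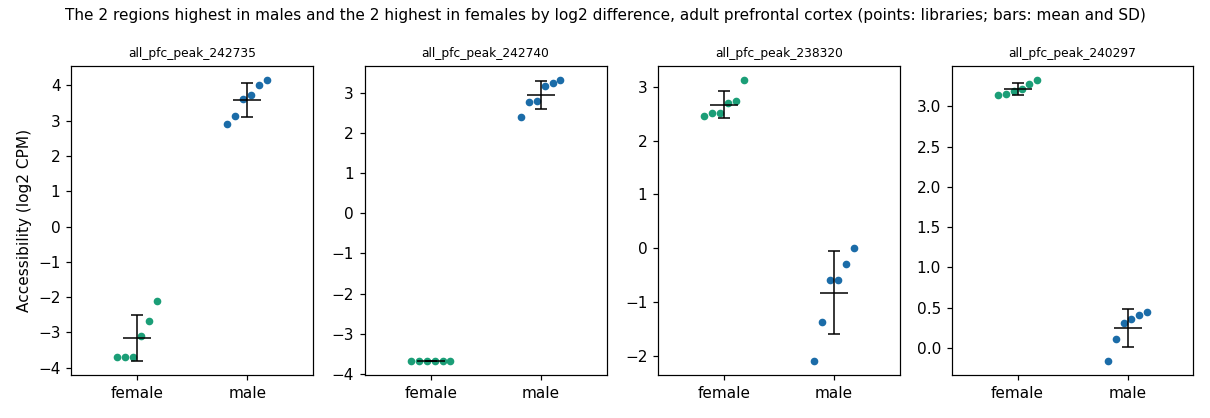
Accessibility in log2 CPM (vertical axis) of the 2 regions with the largest log2 difference toward males and the 2 with the largest toward females, in 6 female and 6 male adult libraries (points), with mean and SD (bars). Males and females do not overlap at any of the 4, and all 6 females lie at the lowest value for all_pfc_peak_242740.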

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

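The tests of the removed directions and of the level trend, and the thresholds set on their counts, were chosen only after the results were seen, and an earlier bound of 100 regions was replaced after its result was known. The tests of the variable block, which was itself defined from the data, and of the number of mutant alleles were chosen after the data were examined but before their own results were seen; the counts of other splits were set out before their results were seen. The simulated spread for the allele test was also chosen afterwards.

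The 29 regions that differed between Hom and Het at E14.5 are taken up because the difference between 2 mutant groups was itself tested. In 2 of 60 splits of the Hom and Het libraries, the real one included, as many regions were called, and the highest other split gave 42, more than the real one, so this count does not exclude chance. Single libraries passed an outlier rule within their group in 3 of 47 groups checked, where chance gives about 2.4. The median level was 1.70 CPM in Hom replicate 65 and in WT replicate 13, against 1.65 to 1.67 CPM in the other libraries of each group. The rounded values of both libraries lie 0.0501 CPM apart, so this gap is about 1 rounding step. The mean of a block of variable regions was 1.57 log2 CPM in WT replicate 10, against -3.31 to -2.14 in the other 5 WT libraries.

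For the E14.5 Het comparison, 1 of 60 splits of the Het and WT libraries gave as many called regions, namely the real one with 1691, and the highest other gave 1184. For the Hom comparison and the allele trend the real count was 0, so all 60 splits gave at least as many whatever they held and the count decides nothing; the highest others were 19 and 42. In the adult, 1 of 40 splits gave as many as the real 803 for Het, with 0 as the highest other. These Het splits were drawn without regard to sex, which the real groups balance, and this may also favour the real grouping. For sex, 1 of 40 gave as many as the real 12543, with 1719 as the highest other. The difference between sexes in the Het effect had a real count of 0, which all 40 splits reach in the same way, and 1 as the highest other. Within males and within females the 10 splits are too few for a share under 0.05, with a real value of 0 and a highest other of 0. The authors' adjustment kept the real groups and no other split, so these splits favour the real grouping, and a small share of them does not by itself exclude chance.

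The first pattern is that E14.5 Het libraries differed from WT at 1691 regions and Hom libraries at 0, although Hom carries 2 mutant alleles; the direct comparison of Hom with Het called 29. The tables argue against the variable block, since 1222 of the 1691 stayed called with its mean as a covariate, and against a level trend as the whole cause: with it removed 492 regions were called (102 without Het replicate 34 to 817 without Het replicate 27), 412 of them among the 1691, and the median change of the 1691 was 0.29 log2 in place of 0.31, with an SE of 0.07 in both. Uncounted removed directions are argued against only as the cause of every Het call, since 170 regions stayed called with them as covariates. In fits without 1 library 38 to 227 of the 1691 stayed called, against 0 to 5 calls for Hom. These counts do not follow the 170 themselves. With the covariates 11.5% of regions had an unadjusted limma p under 0.05, against 5.74% for Hom. Simulated tables without a genotype effect gave 5.10% with factors unrelated to genotype and 28.9% with related ones. Those factors had an assumed strength, so these shares exclude nothing. The other 1521 calls ended. Over all 1691 calls the median fold stayed at 0.31 log2, with a median SE of 0.08 in place of 0.07. For the 1521 these directions cannot be told apart from a genotype effect. The number of mutant alleles predicts a slope of the Hom on the Het effect of at least 1. With shared controls and noise taken off, the slope was 0.349 (jackknife SE 0.294, and 0.161 to 0.533 with single libraries left out). The Hom effect variance was 0.000560, against 0.00869 for Het. With single libraries left out the Hom variance ran from -0.00142 to 0.00115, and a variance cannot lie below 0. The covariance of the Het and Hom effects, 0.003035, is also larger than these variances allow. The noise taken off is therefore too uncertain for these values to decide. In simulations with a true slope of 1 and independent noise, 0 of 100 draws gave a slope as low and 0 a variance gap as large. With noise shared between regions 39 and 24 of 100 did. Those slopes ran from -254.8 to 1198, a spread that mixing only 11 directions at random makes wide, so that simulation cannot decide. The bound set on leave-one-out values leaves out noise shared between regions, as independent noise does, and the allele number cannot be told apart. Unwanted variation that the adjustment kept because it ran along genotype, and the sex of the embryos, also stay open and untested for this pattern.

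The second pattern is the adult Het calls. A level trend is argued against, since 788 of the 803 stayed called with it removed. With the removed directions as covariates 14 of the 803 stayed called, and 1 to 13 of the 803 in every fit without 1 library. Some calls thus outlasted the covariates in every fit, but on as few as 1 region. That does not show that the 14 are free of uncounted directions. The other 789 lost their call, and for them uncounted directions and a small genotype effect cannot be told apart. Over all 803 calls the median fold change stayed at 0.38 log2, with a median SE of 0.11 in place of 0.08. Simulated tables with unrelated directions gave 41 calls and 11.5% of regions at an unadjusted p under 0.05, against the real 803 and 16.3%, at an assumed strength that excludes nothing.

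The adult sex calls kept 3124 of 12543 regions with the removed directions as covariates (212 to 3362 in fits without 1 library) and 12147 with the level trend removed. The other 9419 lost their call to the covariates, and what ended them cannot be told apart. Over all 12543 calls the median fold was 0.36 log2 before and after, with a median SE of 0.11 in place of 0.09. At E14.5, 67.2% of the Het calls were lower, and 28.5% with each library's level trend removed, so the excess of falls went with the level trend.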

How the results depend on the processing

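The fits with removed directions, level trends or the variable block, and the 2 rescaled overlap values, were chosen after the data were examined; the others were fixed before. No named region changed sign in any setting, but their fold changes shrank with a larger pseudocount. The 4 named sex regions stayed called in all 24 settings each; the 4 E14.5 regions lost their call in 4 to 15 of 33, and the adult Het regions in 12 to 16 of 24 or 14 of 25. Unless given here, counts stayed within 1.5 times the reported one, and the cause of a move was not tested. A looser threshold calls more regions by construction. Counts with 1 library left out moved both ways, so it mattered which library was left out. Without a filter the Het comparison called 1058 regions at E14.5 and 371 in the adult, and Hom against Het 15; a filter at 2 CPM gave 44 for Hom against Het. Robust limma gave 18 for Hom against Het. Quantile normalization gave 568 (Het, E14.5), 53 (Hom against Het) and 1242 (adult Het). At an adjusted p under 0.1 the counts were 4536, 100, 4109 and, for sex, 22732. Litter as a block gave 1122 for Het and changed no other E14.5 count by over 1.5 times. Litter 1 alone gave 130 for Het and 12 for Hom against Het. Litter 2 alone gave 29 and 5, 20 for Hom and 15 for the allele trend. Without a sex term adult Het called 4. The removed directions as covariates gave 170 (Het), 18 (Hom against Het), 24 (adult Het), 32 (in males), 14 (difference between sexes) and 3135 (sex). Level trend removal gave 492, 60 and, for adult Het, 1217. Both together gave 107, 47, 28, 30 in males, 1 in females, 12 for the difference between sexes and 3443 for sex. The Het and Hom correlation was 0.51, 0.49 after quantile normalization and 0.50 with the level trend removed. Leaving out 1 library at a time gave 203 to 2232 for Het, 10 to 36 for Hom against Het, 0 to 1 for Hom and 0 to 0 for the allele trend. In the adult it gave 3 to 986 for Het, 5231 to 14693 for sex and 0 to 0 within males, within females and for their difference. Tests without X and Y, of gene lists (with their nearest distances, camera correlation and litter block), of location classes, of motifs and of the overlap between ages were not run. No paired analysis by replicate number was possible because the genotypes share no numbers. Depth is unknown, so what it limits cannot be given.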

Other observations

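The tests in this part were all chosen after the results were seen, and the block and the tail of region numbers were defined from the data.

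A block of 11 regions numbered between 235790 and 235810, which varied by over 5 log2 among embryos and correlated with each other across libraries, averaged -2.17 ± 1.88 log2 CPM in 6 WT, -0.88 ± 2.52 in 5 Het and -0.81 ± 2.95 in 6 Hom libraries (SD). Neither mutant group differed from WT (exact permutation p = 0.359 for Het and 0.331 for Hom). Among the last 25 region numbers of the adult table, 16 tested regions averaged 2.61 ± 0.48 log2 CPM in Het and 1.60 ± 1.06 in WT (SD, n = 6 each, exact permutation p = 0.0649). Of the 3 largest adult Het rises, 2 lay among the last 100 numbers.

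Regions with nearby numbers changed together. At a distance of 50 numbers, the test statistics correlated at 0.0658 for Het and 0.0396 for Hom at E14.5, and at 0.102 for sex and 0.0314 for Het in the adult, while the residual directions reached 0.0182 at most. The adjustment took 3 directions out of the residuals and kept the group contrasts, so the residual directions lost shared structure by construction and are no fair reference. Local structure common to all differences between libraries (0.0658 for E14.5 Het), variation that the adjustment left in the contrasts it protected (0.0314 in the lowest of the 4 comparisons above, though 0.0184 for Hom against Het) and a broad effect of genotype or sex on neighbouring regions may each be a source, and cannot be told apart here. The difference between sexes in the Het effect, most of which was removed, gave 0.00775.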
